A study of Homo sapiens with 8 samples.

How the data were processed

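RNA abundance and ribosome density were measured in MCF7 cells with and without camptothecin, in 2 libraries for each of 4 groups (RNA control, RNA CPT, footprint control and footprint CPT), per the labels. Per the labels' protocols, RNA libraries were made from polyadenylated RNA, and footprint libraries from monosomes of cycloheximide-treated cells after RNase I digestion. Per the submitters' processing notes, Bowtie was used. Its version, the genome build, the annotation and the counting are not given in the sources used here. The deposited table holds RPKM values (reads relative to transcript length and to the mapped reads of the library) made by the authors, for 9792 genes, each with 1 Ensembl transcript and 1 symbol. The unit is named only in the title the authors gave the deposited table. The values are rounded to 1 decimal, and low values stand at exactly 1.0, so genes with few or no reads cannot be distinguished there. Read counts were not used here, whole reads could not be recovered from the rounded values, and the depth of each library is unknown. The symbols are those of the table, and 8989 of the 9792 match a current symbol in the reference list of gene names. Columns were matched to samples by their names, and no other sample columns were present.

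How these values were made bears on what they show. RPKM are shares of a library, so an equal loss of all mRNAs cannot be seen. A value per gene takes in only the listed transcript. Selection for poly(A) tails leaves out most mRNA of replication-dependent histone genes. The floor at 1.0 understates the change of genes near it: 188 of the genes lower in RNA and 232 of those lower in footprints had a CPT library at 1.0.

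Values were scaled within each assay by trimmed-mean factors (30% of log ratios and 5% of mean values trimmed at each end, over genes with no library at 1.0), then taken as log2(scaled RPKM + 1). Fold changes are on this scale, with a pseudocount of 1 that understates the change of low genes, and folds given as such are ratios of mean scaled RPKM. The 8200 genes with a mean deposited RPKM of at least 3 in each assay were tested. All 8 libraries entered a single limma-trend fit (limma 3.58.1, R 4.3.3) with a mean per group and 4 residual degrees of freedom. The contrasts were CPT minus control in RNA, CPT minus control in footprints, and their difference (the interaction, the change of translational efficiency). Tests were two-sided, with Benjamini-Hochberg adjustment over the 8200 genes in each contrast and a threshold of 0.05.

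The count tests planned could not be used, since the unit is RPKM. Each group was given a weight estimated from its duplicates (2.54 for RNA control, 1.3 for RNA CPT, 1.01 for footprint control and 0.3 for footprint CPT). This weighting was chosen after seeing the data, and after its counts of calls had been computed as an alternative, because on simulated values a fit with a single spread made 41 false footprint calls among 213 (19.2%). The single-spread fit made 0 false among 169 RNA calls, fewer than the weighted fit, and 16 among 160 efficiency calls (10%). The fit was tested on simulated data for 8200 genes, 200 of them changed, 50 each by 0.5, 1, 2 and 3 log2 units. For RNA it recovered 94%, 100%, 100% and 100% of these, with 15 false among 212 calls (7.1%). For footprints it recovered 20%, 100%, 100% and 100%, with 14 false among 174 calls (8%). For efficiency it recovered 6%, 86%, 100% and 100%, with 15 false among 161 calls (9.3%), so the false share lay above the nominal 5% in each. The simulated noise was given a separate spread per group, taken from these libraries, which favours the weighted fit. Only 200 of 8200 genes were changed and no scaling step was simulated. These shares are therefore not the false shares of the calls reported here.

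A design with count tests, the alternatives, the rule for named genes and 27 gene lists were fixed before the data were examined. The limma-trend fit, the RPKM filter and the pseudocount took the place of the planned count steps once the table proved to hold RPKM. The lists were p53 targets, immediate-early and AP-1 genes, NF-kB targets, estrogen response, G1/S and replication, G2/M and mitosis, histones, cytoplasmic ribosomal proteins, other TOP mRNAs, translation initiation factors, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, proteasome, splicing factors, chromatin regulators, ZNF genes (every symbol of ZNF and digits), ATF4 and amino acid response, endoplasmic reticulum chaperones, heat shock, m6A machinery, topoisomerases and DNA break repair, cholesterol synthesis, BCL2 family, luminal epithelial markers, and mesenchymal, leukocyte and basal epithelial markers for other cell types. The 23 lists with at least 5 genes tested entered limma's camera with a preset correlation of 0.01, adjusted over the lists within each contrast. With a correlation estimated from the data no list passed in any contrast. Named genes were the 6 largest increases and the 6 largest decreases per contrast among genes past the threshold whose change had the same sign in all 4 pairings of CPT and control libraries (16 combinations for efficiency), up to 4 genes of smallest p from each list, and TOP1, CDKN1A, MDM2, MYC, JUN and METTL3. The count minimum in that rule was replaced by the RPKM filter.

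The slope of footprint on RNA changes used the RNA change of the other replicate as instrument, so that RNA noise does not enter both sides, with 2000 bootstrap draws over genes. Alternatives were other scalings (median-of-ratios, upper-quartile, trimmed-mean over all 8 libraries, none), other filters and pseudocounts, a replicate block, a single spread, each assay alone, and each library left out in turn. A lone library then kept the weight of its group and was assumed to vary like the other groups. The planned analysis of gene length was left out, because it needs counts or a named genome build.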

Results

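MCF7 cells, an estrogen receptor-positive luminal breast cancer line, were compared with and without camptothecin (CPT), a drug that traps topoisomerase I on DNA and so stalls transcription and replication. CPT was given at 6 µM for 5 h. Polyadenylated RNA was sequenced to measure mRNA abundance, and ribosome-protected fragments (footprints) were sequenced to measure ribosome density on the same transcripts. The 4 groups (RNA control, RNA CPT, footprint control, footprint CPT) held 2 libraries each, 8 in all. The table gave an RPKM value for 9792 genes in each library and no read counts, so the sequencing depth is unknown. Median RPKM was 14.3 in both RNA control libraries and 9.1 and 9.3 in RNA CPT, against 19.8 and 19.9 in footprint controls and 13.4 and 13.1 in footprint CPT. The number of genes at 1.0, the lowest value in the table, was 139 and 134 in RNA controls, 826 and 700 in RNA CPT, 62 and 50 in footprint controls and 843 and 829 in footprint CPT. The duplicates were closest in RNA controls (SD of the log2 difference 0.128 across 8200 genes) and farthest apart in footprint CPT (0.329), where 55 genes differed by more than 2-fold. The duplicates are described as biological, without saying whether they were separate cultures, so p-values measure only the spread between these samples.

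The first comparison asked which mRNAs changed in abundance after CPT. The cells treated with CPT had higher mRNA of most immediate-early and AP-1 genes, of ribosomal proteins and of the mitochondrial respiratory chain, and lower mRNA of most mitotic genes, chromatin regulators and zinc finger genes. The p53 targets went both ways. GDF15 (ENST00000252809), a secreted stress cytokine, rose from 7.76 ± 1.68 to 110.6 ± 6.24 scaled RPKM (mean ± SD, n = 2 in each group), 14.2-fold. WDR43 (ENST00000407426), a ribosome biogenesis factor, fell from 39.4 ± 1.51 to 2.58 ± 0.95, 15.3-fold. TTK (ENST00000369798), a mitotic checkpoint kinase, fell from 32.9 ± 3.31 to 2.47 ± 0.16, 13.4-fold. Of 8200 genes tested, 6848 (83.5%) passed an adjusted p of 0.05 in the limma test, 3564 higher and 3284 lower. The larger changes were mostly decreases: 498 of these genes were higher and 1493 lower by 2-fold or more on the log2(scaled RPKM + 1) scale.

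The 6 largest increases on the log2(scaled RPKM + 1) scale were GDF15 (3.68 ± 0.14, SE, adjusted p = 5.95e-10), BTG2, an antiproliferative p53 target (3.47 ± 0.14), and PMAIP1, which encodes the pro-apoptotic protein NOXA (3.39 ± 0.10). They were followed by FOSL1, an AP-1 subunit (3.22 ± 0.08), SERTAD1, a transcriptional coregulator that binds CDK4 (3.22 ± 0.09), and IER5, an immediate-early gene (3.13 ± 0.07). Both RNA controls listed FOSL1 at 1.0, so its change has no measured baseline. The 6 largest decreases were WDR43 (-3.52 ± 0.13), ELF1, an ETS transcription factor that both RNA CPT libraries listed at 1.0 (-3.45 ± 0.09), and TTK (-3.29 ± 0.12). Next came NGDN, a nucleolar protein (-3.24 ± 0.13), PIK3R3, a regulatory subunit of phosphoinositide kinase (-3.24 ± 0.11), and MAPK6, an atypical MAP kinase (-3.20 ± 0.12). Adjusted p of these 12 genes lay between 1.44e-10 and 7.78e-10. The rule for named genes required the same sign in all 4 pairings of a CPT with a control library.

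Among immediate-early and AP-1 genes, 19 of 22 rose and 3 fell, with a median change of 1.19 (adjusted p = 4.63e-05 in camera, adjusted p = 0.38 with an estimated correlation). JUNB rose by 2.70, ATF3 by 2.71 and JUN by 2.20 on the log2 scale, and MYC, a growth-promoting transcription factor, rose by 1.08 ± 0.09 (adjusted p = 2.8e-07). The 29 p53 targets did not move together: 17 rose and 10 fell (median 0.46, adjusted p = 0.121). On the deposited scale the list passed (adjusted p = 0.021). CDKN1A (ENST00000448526), the cyclin-dependent kinase inhibitor p21, rose from 41 ± 4.8 to 193.7 ± 14.7 scaled RPKM (2.22 ± 0.09, adjusted p = 8.58e-10), and GADD45A, a DNA damage-inducible gene, rose from 6.51 ± 0.35 to 59.04 ± 4.24. MDM2 (ENST00000462284), the ubiquitin ligase that targets p53, fell from 29.4 ± 2.29 to 7 ± 1.02 scaled RPKM (-1.93 ± 0.10, adjusted p = 4.47e-09).

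All 78 cytoplasmic ribosomal protein genes tested rose, by a median of 0.90 or 1.87-fold (adjusted p = 4.75e-16, adjusted p = 0.38 with an estimated correlation). So did all 72 nuclear genes of oxidative phosphorylation, by 0.91 or 1.88-fold (adjusted p = 6.26e-15, adjusted p = 0.38 with an estimated correlation). RPLP2 rose by 1.28 ± 0.06, RPS28 by 1.21 ± 0.06, COX8A by 1.44 ± 0.08 and NDUFV1 by 1.22 ± 0.06. Of the other mRNAs with a terminal oligopyrimidine (TOP) tract, most of which encode translation factors, 14 of 16 rose and 1 fell (median 0.68, adjusted p = 0.000594, adjusted p = 0.38 with an estimated correlation). EEF1G rose by 0.88. Of 31 proteasome genes, 25 rose and 3 fell (median 0.51, adjusted p = 0.000286, adjusted p = 0.38 with an estimated correlation), among them PSMD2 (0.98) and PSMA7 (1.04). Of 16 endoplasmic reticulum chaperones, 12 rose and 4 fell (median 0.64, adjusted p = 0.0446, adjusted p = 0.38 with an estimated correlation). PDIA6 rose by 1.00 and HSP90B1 by 0.83. Of 13 histone genes, 8 rose and none fell (median 0.55, adjusted p = 0.0492, adjusted p = 0.55 with an estimated correlation), including the variant genes H2AFJ (1.26) and H1FX (0.92). The 4 mitochondrially encoded mRNAs tested, MT-CO1, MT-CO2, MT-ATP6 and MT-ND4L, also rose, by 2.07-fold to 2.26-fold. Their share of the RPKM sum was 8.55% and 7.84% in RNA controls against 11.3% and 11.89% in RNA CPT.

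Of 42 chromatin regulators, 34 fell and 2 rose (median -1.64, adjusted p = 2.09e-08, adjusted p = 0.38 with an estimated correlation). CHD1 (-3.15), SETD5 (-2.88), ARID2 (-2.77) and CHD2 (-2.43) were the members with the smallest p. Of 30 genes of the G2 phase and mitosis, 28 fell (median -1.18, adjusted p = 7.59e-07, adjusted p = 0.38 with an estimated correlation), including the mitotic kinase AURKA (-3.04), the spindle protein ASPM (-2.52) and the motor KIF11 (-2.68). Of 107 ZNF genes, which encode zinc finger proteins, 66 fell and 26 rose (median -0.56, adjusted p = 0.00246, adjusted p = 0.38 with an estimated correlation), among them ZNF148 (-2.44) and ZNF100 (-2.12), both listed at 1.0 in the RNA CPT libraries. Over genes of at least 10 RPKM their shift was -0.09 (adjusted p = 0.773). Of 15 genes of the machinery of m6A, an mRNA methylation, 12 fell and 1 rose (median -0.53, adjusted p = 0.00368, adjusted p = 0.38 with an estimated correlation). The reader YTHDF2 fell by 2.30 and ZC3H13, a subunit of the methyltransferase complex, fell by 2.15 on the log2 scale. METTL3 (ENST00000298717), the catalytic subunit, was the member that rose, by 0.26 ± 0.08 (adjusted p = 0.00702). With a single spread for all groups METTL3 missed the threshold (adjusted p = 0.0531). Its change was -0.06 (adjusted p = 0.486) on the deposited scale, 0.09 (adjusted p = 0.283) with upper-quartile scaling and 0.23 (adjusted p = 0.057) without RNA CPT replicate 1. Of 26 topoisomerase and DNA break repair genes, 18 fell and 4 rose (median -0.38, adjusted p = 0.0492, adjusted p = 0.38 with an estimated correlation). TOP3A fell by 1.43, BRCA1 fell by 1.10 and TDP1, which removes trapped topoisomerase I, fell by 1.10 on the log2 scale. TOP1 (ENST00000361337), the target of CPT, fell from 85.6 ± 1.18 to 68.5 ± 0.74 scaled RPKM (-0.32 ± 0.11, adjusted p = 0.0188). This call was lost without RNA CPT replicate 1 (-0.31, adjusted p = 0.0809) or replicate 2 (-0.33, adjusted p = 0.0632), and with a single spread for all groups (adjusted p = 0.297).

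The remaining lists did not pass the camera test. For estrogen response genes, 8 of 23 rose and 13 fell (adjusted p = 0.171), with decreases of the luminal transcription factor GATA3 (-2.92) and the nuclear receptor cofactor NRIP1 (-3.12). For cholesterol synthesis, 6 of 18 rose and 9 fell (adjusted p = 0.32), with decreases of LDLR (-2.51) and SQLE (-1.90). Over genes of at least 10 RPKM the cholesterol list passed (adjusted p = 0.049). For translation initiation factors, 16 of 31 rose and 7 fell (adjusted p = 0.144). For splicing factors 25 of 44 rose and 14 fell (adjusted p = 0.171). For heat shock genes 8 of 17 rose and 4 fell (adjusted p = 0.27), and for the BCL2 family 6 of 11 rose and 3 fell (adjusted p = 0.27). For G1/S and replication genes 17 of 30 rose and 8 fell (adjusted p = 0.32). For the ATF4 and amino acid response 12 of 23 rose and 7 fell (adjusted p = 0.363). For NF-kB targets 3 rose and 3 fell (adjusted p = 0.988, with a median of 0.07, a mean of -0.10 and a test on the lower side). Luminal epithelial markers rose in 9 of 13 and fell in 4 (adjusted p = 0.236). Few markers of other cell types were expressed: the 3 mesenchymal genes FN1, COL3A1 and LGALS1 rose, as did the leukocyte gene CORO1A and the basal epithelial genes ITGB4 and KRT17, with changes from 0.45 to 1.21. The call of KRT17 was lost without RNA CPT replicate 2 (0.61, adjusted p = 0.0952), and that of ITGB4 on the deposited scale (0.14, adjusted p = 0.139). The count adjusted over the list alone differed from that over all genes tested in 2 lists, topoisomerases and DNA break repair (4 higher and 19 lower) and the ATF4 response (13 higher and 7 lower).

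These changes are relative to the other genes of a library. The scaling factors of CPT libraries lay at -0.33 (log2) relative to controls, so that dividing by them raised CPT values. On the deposited scale the median gene changed by -0.25 and the calls split into 2285 higher and 4258 lower. Trimmed-mean factors over all 8 libraries ended the calls of histones and of topoisomerases and repair (adjusted p = 0.0521 each) and of endoplasmic reticulum chaperones (adjusted p = 0.0519). A single spread ended the first 2 (adjusted p = 0.0529 and 0.0544), as did the filter at 10 RPKM (adjusted p = 0.141 and 0.167), and RNA libraries only ended that of histones (adjusted p = 0.0614). These calls also ended when 1 library was left out. The call of histones ended without RNA control replicate 1 (adjusted p = 0.126), RNA CPT replicate 2 (adjusted p = 0.0782) or any footprint library (adjusted p = 0.0537 to 0.054). That of topoisomerases and repair ended without RNA control replicate 1 (adjusted p = 0.0717), RNA CPT replicate 2 (adjusted p = 0.0782) or footprint control replicate 1 or 2 (adjusted p = 0.051 and 0.0511). That of endoplasmic reticulum chaperones ended without RNA CPT replicate 2 (adjusted p = 0.0633) or footprint control replicate 1 or 2 (adjusted p = 0.051 and 0.0511).

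**Figure D1:**
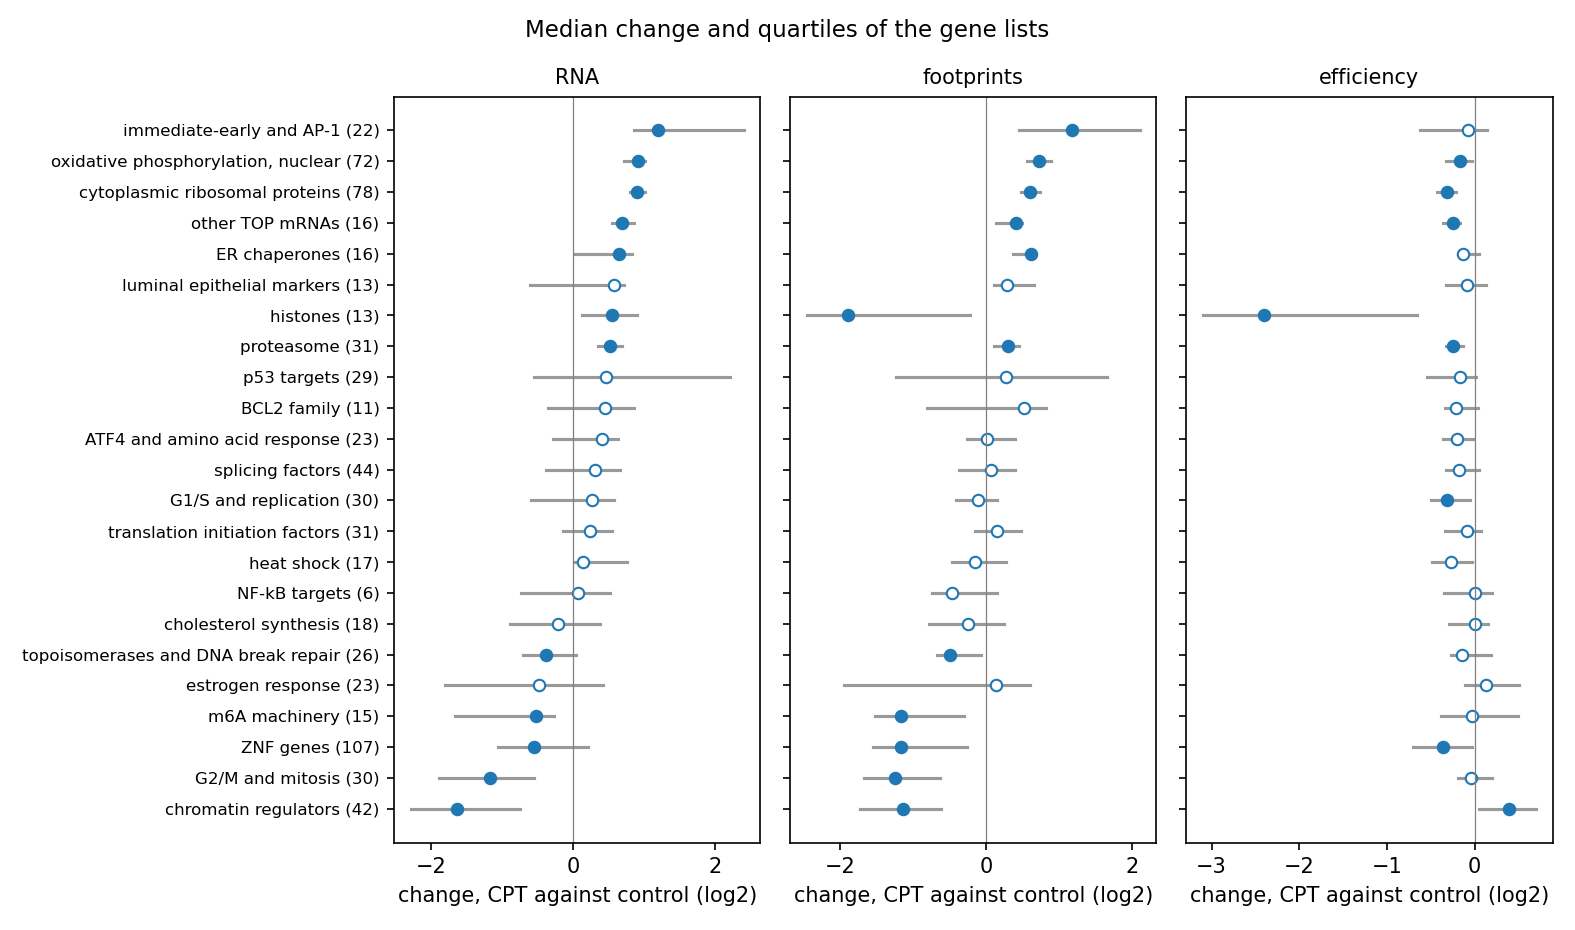
Median log2 change (points) and quartiles (bars) of the 23 gene lists tested (number of genes in brackets), CPT against control, in RNA, footprints and translational efficiency on log2(scaled RPKM + 1). Filled points passed an adjusted p of 0.05 in camera (12, 12 and 8 lists), none with an estimated correlation, and the histone list had a median of 0.55 in RNA, -1.90 in footprints and -2.40 in efficiency.

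The second comparison asked which mRNAs changed in ribosome density. Footprints moved mostly with the RNA: most immediate-early and AP-1, ribosomal protein and respiratory chain genes rose, and most mitotic genes, chromatin regulators and zinc finger genes fell. The poly(A)-binding proteins PABPC1 and PABPC4 departed from this, with footprints that fell and RNA that rose. Footprints of all 16 clustered histone genes fell too, but mRNA of such genes mostly lacks a poly(A) tail and may be left out by the RNA selection used here. One of them, HIST1H2BK, stood at 94.8 scaled RPKM in RNA controls and fell by 0.96 in footprints on the log2 scale. GDF15 footprints rose from 43.3 ± 9.63 to 610 ± 152.7 scaled RPKM (14.1-fold) and those of GATA3 (ENST00000379328) fell from 590.8 ± 44.2 to 52.5 ± 13 (11.2-fold). Of 8200 genes, 5044 (61.5%) passed the limma test, 2404 higher and 2640 lower. By 2-fold or more on the log2(scaled RPKM + 1) scale, 318 of these were higher and 1511 lower.

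The 6 largest increases were FOSL1 (4.01 ± 0.16, adjusted p = 9.12e-08), GDF15 (3.78 ± 0.28) and FOS, an AP-1 subunit that 1 of the footprint controls and both RNA controls listed at 1.0 (3.62 ± 0.20). GADD45A (3.29 ± 0.16), BTG2 (3.29 ± 0.27) and PMAIP1 (3.18 ± 0.20) followed. FOSL1 stood at 1.5 and 1.3 deposited RPKM in the footprint controls, near the floor of 1.0, so the size of its change is uncertain. The 6 largest decreases were NGDN (-3.87 ± 0.25), PPP1R10, a nuclear targeting subunit of protein phosphatase (-3.76 ± 0.25), and CSTF1, a subunit of the cleavage stimulation factor (-3.59 ± 0.20). PIK3R3, listed at 1.0 in both footprint CPT libraries (-3.50 ± 0.21), GATA3 (-3.48 ± 0.19) and PRR15L (-3.44 ± 0.19) followed. Adjusted p of these 12 genes reached at most 2.02e-06.

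Oxidative phosphorylation genes rose in 62 of 72 cases (median 0.72, adjusted p = 1.69e-13, adjusted p = 0.52 with an estimated correlation), among them ATP5J2 (1.14) and NDUFB11 (1.07). Ribosomal proteins rose in 71 of 78 cases (median 0.59, adjusted p = 3.2e-11, adjusted p = 0.52 with an estimated correlation), for instance RPS2 (1.03) and RPL36 (0.95), and fell for RPSA (-0.68) and RPS12 (-0.32). Immediate-early and AP-1 genes rose in 16 of 22 cases and fell in 4 (median 1.17, adjusted p = 3.8e-05, adjusted p = 0.30 with an estimated correlation), with JUN at 1.18 ± 0.19 (adjusted p = 0.000229) and MYC at 1.00 ± 0.18 (adjusted p = 0.000453). Of 16 endoplasmic reticulum chaperones 12 rose and DNAJB9 fell (-1.26; median 0.61, adjusted p = 0.00507, adjusted p = 0.52 with an estimated correlation). Of 31 proteasome genes 14 rose and 2 fell (median 0.29, adjusted p = 0.0173, adjusted p = 0.54 with an estimated correlation), with PSMD8 at 0.75. Of the other TOP mRNAs 11 of 16 rose, including EEF1A1 (0.67), while PABPC1 fell (-3.25 ± 0.16; list median 0.41, adjusted p = 0.0429, adjusted p = 0.54 with an estimated correlation). These last 2 lists missed the threshold on the deposited scale (adjusted p = 0.15 for the proteasome and 0.143 for other TOP mRNAs) and with upper-quartile scaling (adjusted p = 0.0775 and 0.0912). Over genes of at least 10 RPKM their shifts were 0.04 (adjusted p = 0.289) and 0.17 (adjusted p = 0.325). The 4 mitochondrially encoded mRNAs rose, by 2.53-fold to 3.23-fold, and made up 0.05% and 0.07% of the RPKM sum in footprint controls against 0.14% and 0.10% in footprint CPT. Their footprints per RNA in controls were only 0.0035 to 0.028, against a median of 1.56 over all genes tested. Whether so few reads reflect ribosomes on these mRNAs was not tested.

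Chromatin regulators fell in 34 of 42 cases and none rose (median -1.14, adjusted p = 7.19e-09, adjusted p = 0.52 with an estimated correlation), with CHD8 at -2.54 and the histone demethylase KDM2A at -2.42. ZNF genes fell in 71 of 107 cases and rose in 13 (median -1.17, adjusted p = 9.46e-08, adjusted p = 0.30 with an estimated correlation), with ZNF146 at -2.52. Mitotic genes fell in 28 of 30 cases (median -1.25, adjusted p = 1.72e-07, adjusted p = 0.52 with an estimated correlation), with AURKA at -3.22 and PLK1 at -2.15. Of 15 m6A genes 10 fell and 1 rose (median -1.17, adjusted p = 0.00526, adjusted p = 0.52 with an estimated correlation), with YTHDF2 at -3.20. METTL3 footprints did not pass the test (-0.22 ± 0.15, adjusted p = 0.206), though they did on the deposited scale (-0.50, adjusted p = 0.0126) and with upper-quartile scaling (-0.40, adjusted p = 0.0355). Of 13 histone genes 9 fell and 2 rose (median -1.90, adjusted p = 0.018, adjusted p = 0.54 with an estimated correlation), with HIST1H1C, a linker histone, at -2.69 ± 0.21. Of 26 topoisomerase and repair genes 14 fell and none rose (median -0.50, adjusted p = 0.0225, adjusted p = 0.52 with an estimated correlation), with RNF168 at -1.91. Among the single genes, CDKN1A rose by 1.65 ± 0.18 (adjusted p = 1.24e-05), MDM2 fell (-1.24 ± 0.19, adjusted p = 0.000187), and the anti-apoptotic gene MCL1 fell (-1.96 ± 0.13, adjusted p = 5.01e-07).

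The other lists did not pass. Of 29 p53 targets 12 rose and 11 fell, of 13 luminal markers 5 and 2, and of 31 initiation factors 12 and 4 (adjusted p = 0.237 each). The BCL2 family had 7 genes higher and 3 lower (adjusted p = 0.287), and heat shock genes 4 and 5 (adjusted p = 0.924). Cholesterol synthesis had 2 higher and 8 lower (adjusted p = 0.262), and passed over genes of at least 10 RPKM (adjusted p = 0.025). The ATF4 response had 4 higher and 5 lower (adjusted p = 0.723). G1/S and replication had 6 and 7, and NF-kB targets 1 and 3 (adjusted p = 0.545 each). Splicing factors had 12 and 11 (adjusted p = 0.558), with a median of 0.06 and a mean of -0.05. Estrogen response had 7 and 9 (adjusted p = 0.641), with a median of 0.13, a mean of -0.52 and a test on the lower side. Of the markers of other cell types, FN1 (0.77) and COL3A1 (1.07) rose. Both calls were lost without footprint CPT replicate 1 (0.45, adjusted p = 0.0853, and 0.65, adjusted p = 0.0795). LGALS1 and CORO1A did not pass. ITGB4 missed the threshold (0.39, adjusted p = 0.0505), and passed with trimmed-mean factors over all 8 libraries (adjusted p = 0.0224), a single spread (adjusted p = 0.0217) or footprint libraries only (adjusted p = 0.0449). It also passed without footprint control replicate 2 (0.48, adjusted p = 0.0383) or footprint CPT replicate 2 (0.57, adjusted p = 0.0426). KRT17 missed it as well (0.73, adjusted p = 0.279), and passed with footprint libraries only (adjusted p = 0.0402). With the replicate block both KRT17 (adjusted p = 0.00274) and ITGB4 (adjusted p = 0.0456) passed. The count adjusted over the list alone differed in 8 lists. It was 64 higher for oxidative phosphorylation, 13 higher and 73 lower for ZNF genes, 13 and 1 for the proteasome and 0 and 12 for topoisomerases and repair. It was 10 and 4 for initiation factors, 5 and 7 for G1/S, 4 and 4 for the ATF4 response and 1 and 8 for cholesterol synthesis.

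TOP1 footprints were 143.3 and 148.7 scaled RPKM in controls and 68.2 and 146.6 in CPT. The decrease (-0.54 ± 0.21, adjusted p = 0.0456) missed the threshold with trimmed-mean factors over all 8 libraries (-0.47, adjusted p = 0.0742) and without a filter (-0.54, adjusted p = 0.0638). It rested on footprint CPT replicate 1. Without that library it was 0.01 (adjusted p = 0.977), and without footprint CPT replicate 2 it was -1.09. It also missed the threshold without footprint control replicate 1 (-0.57, adjusted p = 0.0776) or 2 (-0.51, adjusted p = 0.106) or RNA CPT replicate 1 (-0.54, adjusted p = 0.0556) or 2 (-0.54, adjusted p = 0.0555), and with a single spread for all groups (adjusted p = 0.0916). Leaving out footprint CPT replicate 2 ended the call of histones (-1.71, adjusted p = 0.0977) and of other TOP mRNAs (0.33, adjusted p = 0.163). The latter call was also lost without RNA control replicate 1 or 2 (adjusted p = 0.0528 each) or footprint control replicate 1 (adjusted p = 0.0625) or 2 (adjusted p = 0.0531). Leaving out footprint CPT replicate 1 ended that of topoisomerases and repair (-0.45, adjusted p = 0.105). The scaling factors of CPT footprint libraries lay at -0.29 (log2) relative to controls, and dividing by them raised CPT values. On the deposited scale the median gene changed by -0.24 and the calls split into 1279 higher and 3430 lower, and with upper-quartile scaling into 1690 and 3135.

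**Figure D2:**
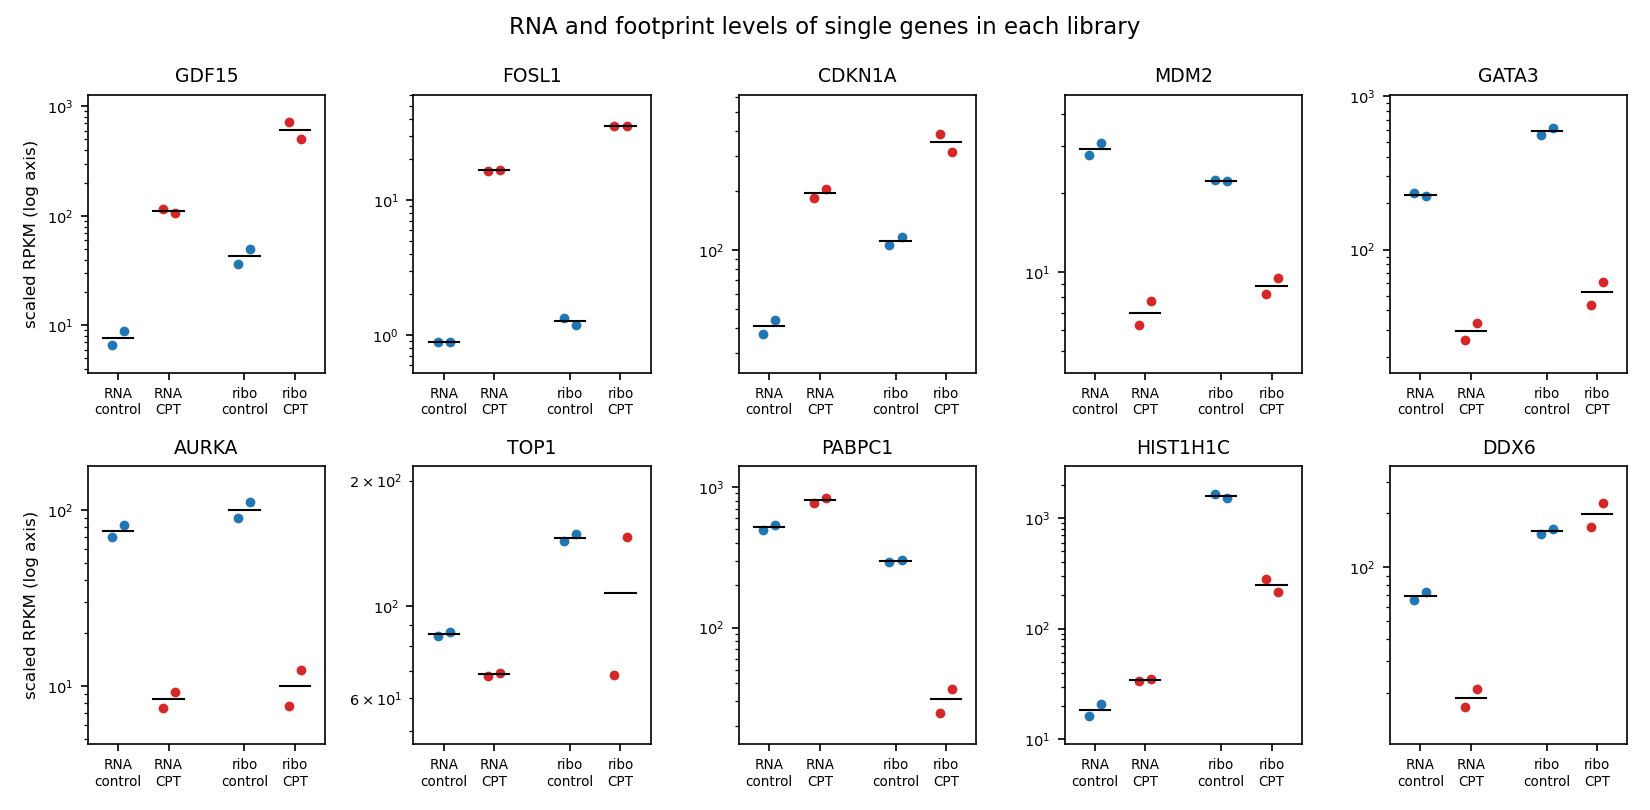
RNA and footprint level of 10 genes in each library, as scaled RPKM on a log axis, with points for single libraries (2 per group, control blue, CPT red) and lines for their means. Footprints of PABPC1 and HIST1H1C fell while their polyadenylated RNA rose, DDX6 RNA fell while its footprint change of 0.30 did not pass the test, and the CPT footprint libraries of TOP1 were 68.2 and 146.6.

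The third comparison asked whether footprints changed by more or less than the RNA of the same gene, that is, whether translational efficiency (footprints per RNA) changed. Efficiency fell for PABPC1 and PABPC4 (-3.88 and -3.87), and by less for 15 of 78 ribosomal protein and 31 of 107 ZNF genes, and rose for 13 of 42 chromatin regulators and for DDX6 (ENST00000264018), a DEAD-box helicase of mRNA decay. The ratio of footprints to polyadenylated RNA also fell for all 16 clustered histone genes. Their median ratio in controls lay 5.95 log2 units above that of all genes tested. PABPC1 (ENST00000318607) RNA rose from 519.3 ± 29.6 to 804.7 ± 53.2 scaled RPKM while its footprints fell from 296.3 ± 6.56 to 30.8 ± 8.44, 9.62-fold. DDX6 RNA fell from 69.4 ± 5.13 to 18.8 ± 3.13 while its footprints were at 158.6 ± 7.17 and 198.1 ± 44. In the interaction test of the limma fit, 1365 of 8200 genes (16.6%) passed, 631 higher and 734 lower. By 2-fold or more on the log2 scale, 154 of these were higher and 276 lower.

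The 6 largest decreases of footprints per RNA were those of HIST1H3H (ENST00000369163; -4.04 ± 0.22, adjusted p = 9.6e-07), PABPC1 (-3.88 ± 0.18, adjusted p = 6.28e-07) and PABPC4 (ENST00000372858; -3.87 ± 0.20, adjusted p = 8.9e-07). They were followed by HIST1H1C (-3.57 ± 0.24, adjusted p = 5.18e-06), HIST1H2AM (-3.35 ± 0.25, adjusted p = 1.13e-05) and HIST1H2AE (-3.34 ± 0.37, adjusted p = 0.000213). PABPC1 and PABPC4 are similar in sequence, as are the histone genes of a class, and how the authors placed reads that match several genes is not given in the sources used here. The 6 largest increases were ATXN7, a subunit of the SAGA complex (2.68 ± 0.50, adjusted p = 0.00474), DDX6 (2.14 ± 0.22, adjusted p = 0.000114) and AMMECR1 (2.13 ± 0.32, adjusted p = 0.00134). Next came MEGF9 (1.96 ± 0.23, adjusted p = 0.000333), PPP3R1, the regulatory subunit of calcineurin (1.90 ± 0.20, adjusted p = 0.000121), and PRLR, the prolactin receptor (1.88 ± 0.24, adjusted p = 0.000532). The ATXN7 call was lost without footprint CPT replicate 2 (1.75, adjusted p = 0.0798), and the 2 CPT footprint libraries of ATXN7 stood at 33.1 and 122.5 scaled RPKM. AMMECR1 stood at 45.4 and 123.3, and its change was 1.42 (adjusted p = 0.0107) without footprint CPT replicate 2 and 2.84 without replicate 1.

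Of 13 histone genes, 11 fell in footprints per polyadenylated RNA and none rose (median -2.40, adjusted p = 6.96e-11, adjusted p = 0.53 with an estimated correlation), with HIST1H2BD at -2.45 and HIST2H2BE at -3.15. Ribosomal protein genes fell in 15 of 78 cases and none rose (median -0.31, adjusted p = 1.98e-08, adjusted p = 0.72 with an estimated correlation). RPSA fell by 1.73, RPS12 by 1.45 and RPL12 by 1.01 on the log2 scale. ZNF genes fell in 31 of 107 cases and rose in 4 (median -0.36, adjusted p = 6.15e-06, adjusted p = 0.53 with an estimated correlation), with ZNF707 at -2.84 and ZNF12 at -1.67. Chromatin regulators rose in 13 of 42 cases and fell in 4 (median 0.39, adjusted p = 0.0015, adjusted p = 0.72 with an estimated correlation). MED13 (1.82), MED13L (1.30) and SETD5 (1.00) rose and KDM2A fell (-2.37). Over genes of at least 10 RPKM the shift of this list was 0.14 (adjusted p = 0.87). The other TOP mRNAs fell in 4 of 16 cases (median -0.25, adjusted p = 0.0026, adjusted p = 0.72 with an estimated correlation), PABPC1 among them. Over all genes tested, 734 of 8200 fell in efficiency. Where the 2 measures used different RNA replicates, genes with an RNA change of 0.5 to 1 had efficiency medians of -0.13 and -0.18. The efficiency median of -0.16 for oxidative phosphorylation, whose RNA median was 0.91, lay between these. Those of ribosomal proteins (-0.31), other TOP mRNAs (-0.25) and the proteasome (-0.25) lay below both, at RNA medians of 0.90, 0.68 and 0.51. Genes with an RNA change of -2 to -1 had efficiency medians of 0.12 and 0.20, against 0.39 for chromatin regulators (RNA median -1.64). Genes from -1 to -0.5 had 0.10 and 0.11, whereas ZNF genes (RNA median -0.56) had -0.36. The proteasome fell in 3 of 31 cases (median -0.25, adjusted p = 0.00709, adjusted p = 0.72 with an estimated correlation), a call lost without RNA CPT replicate 1 (-0.16, adjusted p = 0.0584). Oxidative phosphorylation genes fell in 4 of 72 cases (median -0.16, adjusted p = 0.008, adjusted p = 0.84 with an estimated correlation), lost without RNA CPT replicate 1 (-0.09, adjusted p = 0.162) or footprint CPT replicate 2 (-0.10, adjusted p = 0.102). G1/S and replication genes fell in 5 of 30 cases and rose in 1 (median -0.31, adjusted p = 0.00905, adjusted p = 0.72 with an estimated correlation), lost without footprint CPT replicate 1 (-0.12, adjusted p = 0.219).

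Among genes of lists that did not pass, MCL1 (-1.36), the immediate-early gene KLF6 (-1.70), and the p53 targets AEN (-1.72) and TP53INP1 (-2.04) fell in efficiency. So did the NF-kB inhibitor NFKBIE (-2.49), RBM15, a cofactor of m6A deposition (-1.68), and the initiation factor EIF5 (-0.94), whereas KITLG (1.61) and SEL1L (0.97) rose. The changes of TOP1 (-0.22 ± 0.24, adjusted p = 0.573), CDKN1A (-0.57 ± 0.20, adjusted p = 0.0759), MYC (-0.08 ± 0.20, adjusted p = 0.831) and METTL3 (-0.48 ± 0.17, adjusted p = 0.0678) did not pass. Without footprint CPT replicate 2 that of TOP1 was -0.77 (adjusted p = 0.0265), and without replicate 1 it was 0.32 (adjusted p = 0.26). That of CDKN1A was -0.69 without RNA control replicate 2, and it passed with the replicate block (-0.57, adjusted p = 0.00926). JUN fell (-1.02 ± 0.21, adjusted p = 0.00799), a call lost without footprint CPT replicate 1 (-0.88, adjusted p = 0.101). MDM2 rose (0.69 ± 0.22, adjusted p = 0.0482), and missed the threshold without a filter (adjusted p = 0.0505) or over genes of at least 10 RPKM (adjusted p = 0.0502). This call was lost without RNA control replicate 2 (0.62, adjusted p = 0.0879), RNA CPT replicate 1 (0.56, adjusted p = 0.107), or footprint control replicate 1 (0.70, adjusted p = 0.0917) or 2 (0.68, adjusted p = 0.10). It was also lost without footprint CPT replicate 1 (0.78, adjusted p = 0.136) or 2 (0.60, adjusted p = 0.238), and with pseudocounts of 0.1 (adjusted p = 0.0519) and 0 (adjusted p = 0.0525). The list of heat shock genes, of which 4 of 17 fell, missed the threshold (adjusted p = 0.0508). It passed without RNA control replicate 2 (adjusted p = 0.0461), RNA CPT replicate 1 (adjusted p = 0.0417) or footprint CPT replicate 2 (shift -0.56, adjusted p = 0.000107). It also passed with trimmed-mean factors over all 8 libraries (adjusted p = 0.0416), over genes of at least 10 RPKM (adjusted p = 0.0492) and with the replicate block (adjusted p = 0.0466). Of 23 estrogen response genes 6 rose and 2 fell (adjusted p = 0.179). Of 44 splicing factors 3 rose and 7 fell (adjusted p = 0.182), and without footprint CPT replicate 2 this list passed (shift -0.15, adjusted p = 0.0286). The p53 targets (3 rose and 4 fell of 29), immediate-early and AP-1 genes (2 and 6 of 22) and ATF4 response (1 and 2 of 23) each had an adjusted p of 0.214, and the AP-1 list passed over genes of at least 10 RPKM (adjusted p = 0.037). Initiation factors (2 and 3 of 31) and the BCL2 family (0 and 1 of 11) had an adjusted p of 0.572. Topoisomerases and repair (0 and 4 of 26) had 0.575. Cholesterol synthesis (1 and 2 of 18), luminal markers (1 and 0 of 13) and NF-kB targets (1 and 1 of 6, with a median of 0 and a mean of -0.32) each had an adjusted p of 0.804. Chaperones of the endoplasmic reticulum (2 and 0 of 16) and m6A machinery (2 and 3 of 15) each had an adjusted p of 0.925. In G2/M and mitosis 3 of 30 rose and 2 fell (adjusted p = 0.804), with a median of -0.04 and a mean of 0.02, and without footprint CPT replicate 1 this list shifted by 0.18 (adjusted p = 0.0435). The chaperones had a median of -0.13 and a mean of 0.03, and the m6A genes, tested as higher, a median of -0.03 and a mean of -0.05. In the main fit none of the mitochondrially encoded, mesenchymal, leukocyte or basal genes passed. With the replicate block MT-ATP6 (0.56, adjusted p = 0.0216), LGALS1 (-0.46, adjusted p = 0.0367) and CORO1A (-0.64, adjusted p = 0.0344) did. Without RNA control replicate 1 the change of CORO1A was -0.84. The count adjusted over the list alone differed in 14 lists, among them histones (12 lower), ribosomal proteins (20 lower), ZNF genes (7 higher and 38 lower) and chromatin regulators (18 higher and 7 lower). It also differed for G1/S (1 higher and 7 lower), oxidative phosphorylation (1 lower) and the proteasome, where no gene passed.

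RNA and footprint calls overlapped. In both assays 2193 genes were higher and 2326 lower, against 1044.9 and 1057.3 for independent lists. The calls went opposite ways for 117 and 41 genes. Across the 8200 genes, footprints changed by 0.829 log2 units per log2 unit of RNA change (95% bootstrap interval over genes 0.817 to 0.843, with the RNA change of the other replicate as instrument). The log2 changes correlated with a Pearson r of 0.845 and a Spearman rho of 0.845 across genes, which are not independent replicates. Of the 631 genes of higher efficiency 546 had lower RNA, and of the 734 of lower efficiency 366 had higher and 259 lower RNA. RNA enters both measures there, so the RNA change was also taken from RNA replicate 1 and the efficiency from RNA replicate 2. The median efficiency change was then 0.27 in the 328 genes with an RNA change of -2 or lower, 0.12 in the 1221 between -2 and -1, and -0.20 in the 517 between 1 and 2. It was -0.05 in the 37 genes above 2, nearer 0 than in the class below. With the replicates swapped these medians were 0.36 (265 genes), 0.20 (1184), -0.26 (434) and -0.17 (34).

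Left-out libraries moved the efficiency calls most: 511 genes passed without footprint CPT replicate 1 and 566 without replicate 2, and 492 and 514 of these were among the 1365. On the deposited scale the calls split into 700 higher and 643 lower.

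**Figure D3:**
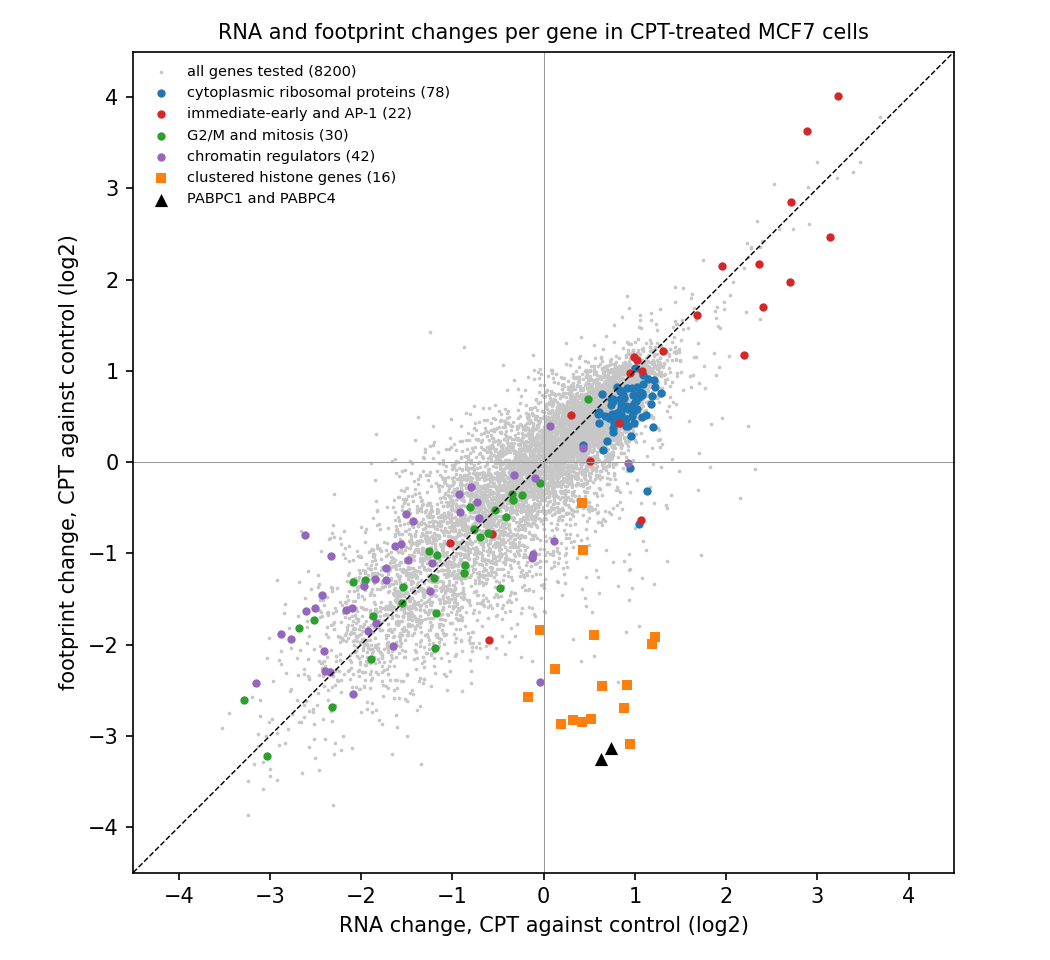
Footprint change against RNA change of each of the 8200 genes tested, CPT against control, both on the log2(scaled RPKM + 1) scale, with equal change as a dashed line. Coloured points mark 4 gene lists, orange squares 16 clustered histone genes and triangles PABPC1 (0.63 in RNA, -3.25 in footprints) and PABPC4 (0.73 and -3.13), which lie far below the line.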

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

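Of the tests weighed here, those of poly(A) selection, of RNA noise in the slope and both tests on PABPC1 and PABPC4 were chosen after the result was seen. Each of the following lists was picked out because its efficiency change differed from that of the other genes tested, in camera. Their median log2 changes of efficiency were: histones (-2.40), ZNF genes (-0.36), G1/S and replication (-0.31), ribosomal proteins (-0.31), other TOP mRNAs (-0.25), proteasome (-0.25), oxidative phosphorylation (-0.16) and chromatin regulators (0.39). None of these calls held with an estimated correlation (adjusted p = 0.53 to 0.84).

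Footprints of all 16 clustered histone genes tested fell (median -2.45) while 11 rose and none fell in RNA (median 0.48). Of 10 variant histone genes, whose mRNAs can carry a poly(A) tail, 7 rose in footprints and 2 fell in efficiency (median -0.12). The 2 sets overlapped in footprints per RNA in controls, with 13.9 for H2AFX and 23.1 for H2AFJ against 8.58 for the clustered gene HIST1H2BK. Exchange of reads among the 16 clustered genes is argued against by their summed footprints. These fell from 19276 and 18170 scaled RPKM to 4129 and 3035, with a mean log2 ratio of -2.40 and from -2.67 to -2.14 in the 4 pairings. Near-identical copies that were not tested, such as HIST1H3B, were not in this sum. A move of reads to such copies would lower it too and stays open. Poly(A) selection may account for the RNA side. In controls the median footprints per RNA of the clustered genes lay 5.95 log2 units above that of all genes, which goes with RNA libraries that hold little of their mRNA. The efficiency change of these genes may then not reflect their translation, and the lower footprints could follow a loss of their mRNA during the drug treatment, which stays open as untested.

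Footprints changed by 0.829 log2 units per log2 unit of RNA, below 1. RNA measurement noise is argued against by this slope itself, which uses separate RNA replicates and had an upper limit of 0.843 over genes. That limit leaves out the spread between libraries. The 2 directions of the instrument gave 0.807 and 0.852. Leaving out footprint CPT replicate 1 or 2 gave 0.78 and 0.879, also below 1. Compression by the floor at 1.0 and the pseudocount is argued against by a slope of 0.771 (0.744 to 0.798) in 3148 genes of at least 30 RPKM without pseudocount. A slower response of ribosome density than of RNA to the drug remains a hypothesis that was not tested, and over the 1352 genes without an RNA call the slope was 1.089 (0.804 to 1.366).

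Footprints of PABPC1 and PABPC4 fell (-3.25 and -3.13) while their RNA rose (0.63 and 0.73). A response shared by TOP mRNAs is argued against by the other 15 TOP mRNAs, whose median efficiency change was -0.25 (-0.68 to 0.01), and by the 78 ribosomal proteins, TOP mRNAs too, with a median of -0.31, of which RPSA (-1.73), RPS12 (-1.45), RPL12 (-1.01) and RPLP1 (-0.82) lay below that range. PABPC1 footprints assigned to PABPC4 cannot be told apart from a decrease of both: the PABPC4 to PABPC1 ratio was 0.281 in control and 0.279 in CPT footprints (a quotient of 0.993), above 0.123 and 0.132 in RNA, and the placing of shared reads is not given in the sources used here. An effect of the drug on both mRNAs stays open as untested.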

How the results depend on the processing

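Settings chosen after seeing the data were the weight per group, the filter at 10 RPKM, a pseudocount of 0, the slopes without genes at 1.0 and above 30 RPKM, and the slopes without a footprint library. The depth is unknown, so its limit on single values was not quantified. The counts of changed genes stayed within 1.5 times of 6848 for RNA, 5044 for footprints and 1365 for efficiency under all scalings, pseudocounts, no filter, a single spread (6098, 5841 and 1432) and separate fits (6803 and 5119). With at least 10 RPKM, which left 5034 genes to test, they were 4264, 3112 and 686. Most of these were higher, with 2840 higher and 1424 lower in RNA and 2024 and 1088 in footprints, but 313 and 373 in efficiency. Left-out libraries gave 6350 to 6830 for RNA, 3503 to 5074 for footprints and 511 to 1264 for efficiency. The replicate number as a block gave 7259, 5219 and 1836, and brought past the threshold the efficiency changes of CDKN1A (adjusted p = 0.00926), MT-ATP6 (0.0216), LGALS1 (0.0367), CORO1A (0.0344) and the heat shock list (0.0466), and the footprint changes of ITGB4 (0.0456) and KRT17 (0.00274). It changed no other call of a named gene or list. The labels do not say that a number marks a shared culture, and replicate differences correlated at 0.54 between RNA control and RNA CPT and at 0.07 between footprint control and footprint CPT. Across assays they correlated at 0.40 and 0.20 for RNA control with footprint control and CPT, and at 0.34 and 0.21 for RNA CPT. The count of lists went from 12, 12 and 8 to 0, 0 and 0 with an estimated correlation. This setting inflates the variance of a list whose genes vary together, but adjusted p also rose where the estimate was small. In RNA it went from 4.63e-05 to 0.38 for immediate-early and AP-1 genes (estimate 0.05). It went from 0.121 to 0.38 for p53 targets (estimate 0.01, as preset). Genes that vary together may therefore not account for the whole loss. In limma's rotation test fry, which does not set a list against other genes, the count of lists was 21 for RNA, 18 for footprints and 4 for efficiency. In efficiency fry did not call ribosomal proteins, G1/S and the proteasome (adjusted p = 0.12 each), chromatin regulators (adjusted p = 0.13) or oxidative phosphorylation (adjusted p = 0.22). It called NF-kB targets instead (adjusted p = 0.028). The slope was 0.78 to 0.879 without a footprint library and 1.089 (0.804 to 1.366) over the 1352 genes without an RNA call. The following changes of sign concern lists and genes that missed the threshold on both sides, save METTL3 RNA, TOP1 footprints, TOP1 efficiency without footprint CPT replicate 2 (-0.77, adjusted p = 0.0265) and the G2/M efficiency shift without footprint CPT replicate 1 (0.18, adjusted p = 0.0435), and the cause was not tested. Deposited scale: METTL3 RNA -0.06 and G2/M efficiency 0, the latter also 0.01 with trimmed-mean factors over all 8 libraries. No filter, which equals a mean of at least 1 RPKM: NF-kB RNA -0.20 and efficiency -0.11, and ATF4 footprints 0.08. At least 10 RPKM: RNA of G1/S -0.03, initiation factors -0.08, splicing -0.01 and heat shock -0.15, and footprints of estrogen response -0.03, initiation factors -0.11 and splicing -0.19. Pseudocounts of 0.1 and 0: NF-kB RNA 0 and 0, m6A efficiency -0.03 and -0.03. Ranges over left-out libraries were, for RNA, NF-kB -0.05 to 0.08. For footprints they were TOP1 -1.09 to 0.01, estrogen response -0.02 to 0.20, G1/S -0.27 to 0.07, splicing -0.01 to 0.10, ATF4 -0.06 to 0.11 and heat shock -0.34 to 0.08. For efficiency they were TOP1 -0.77 to 0.32, MYC -0.18 to 0.03, KRT17 -0.84 to 0.13, ITGB4 -0.23 to 0.12, AP-1 -0.12 to 0.01, NF-kB -0.05 to 0.12, G2/M -0.21 to 0.18, chaperones -0.18 to 0.04, m6A -0.13 to 0.23, topoisomerases -0.17 to 0.07, cholesterol -0.10 to 0.05, BCL2 -0.25 to 0.07 and luminal markers -0.14 to 0.04. Of the named genes past the threshold, 108 of 111 in RNA, 100 of 105 in footprints and 37 of 87 in efficiency stayed past it without each single library. The count tests, the mean count of 100 and the gene length analysis were not run, because the table holds RPKM.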

Other observations

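The family comparison and the choice of families were made after the data were examined. Genes were grouped by the letters that open their symbols, and 54 families with at least 15 genes tested were compared in camera, adjusted over the families. In RNA, the KIF family of kinesin motors fell in 17 of 21 cases and rose in 2 (median -1.27, adjusted p = 0.000348, adjusted p = 0.55 with an estimated correlation). The USP family of deubiquitinases fell in 24 of 31 and rose in 4 (median -0.80, adjusted p = 0.000694, adjusted p = 0.54 with an estimated correlation). In efficiency, the ZBTB family of zinc finger transcription factors fell in 8 of 18 cases (median -0.55, adjusted p = 0.00375, adjusted p = 0.33 with an estimated correlation). Efficiency rose for SLC transporters (20 of 133 rose and 7 fell, median 0.21, adjusted p = 0.00279, adjusted p = 0.79 with an estimated correlation). It also rose for TMEM transmembrane proteins (21 of 111 rose and 5 fell, median 0.17, adjusted p = 0.00375, adjusted p = 0.33 with an estimated correlation) and RAB GTPases of vesicle traffic (9 of 45 rose and 3 fell, median 0.17, adjusted p = 0.0131, adjusted p = 0.33 with an estimated correlation).

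A hypothesis from the SLC and TMEM families, written before its test, was that mRNAs of other membrane protein families may share the rise. Their 98 genes had a median efficiency change of 0.08 against -0.04 for the other genes, with 8 higher and 3 lower (p = 0.028 in camera, p = 0.46 with an estimated correlation). The preset correlation put this past 0.05 and the estimated correlation did not, and in RNA the same genes had a median change of 0.36.

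Some genes differed strongly between the 2 footprint libraries of CPT-treated cells. FUS, an RNA-binding protein, stood at 136 and 377.7 scaled RPKM, DHX9, an RNA helicase, at 54.4 and 145.7, and BLCAP at 13.1 and 3.31. These genes were chosen after their values were seen.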
